A study of Sus scrofa with 12 samples.

How the data were processed

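The measurements are RNA sequencing counts from cultured smooth muscle cells of porcine (Sus scrofa) coronary artery. The design text says that the cells were isolated from 3 different animals. Per the labels' protocols, cells between passages 6 and 11 were plated at 60 cells/mm2 in 35 mm dishes in medium with 10% fetal calf serum. After 24 h they received PDGF-BB at 30 ng/ml, S100A4 protein at 1 µg/ml, or both, and RNA was taken 4 h later. The design text writes the protein as oS100A4 and does not spell the prefix out, so it is called S100A4 here. Control cells received neither protein. Each of the 4 groups had 3 libraries, 12 in all. Per the labels, libraries followed the TruSeq RNA protocol and were sequenced as single-end reads of 100 nt on a HiSeq4000.

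The deposited table holds whole-number read counts per gene, not normalized, for 21153 genes given by Ensembl identifier. Per the submitters' processing notes, the authors' processing used CASAVA 1.8.2, STAR 2.4, featureCounts 1.4.6 and the genome build Sscrofa11.1. The role and settings of each tool, the annotation release, the use of strand and the treatment of reads with several matches are not given in the sources used here. Counts of near-identical gene copies, of overlapping genes and of antisense partners are therefore uncertain. Every sample column carried a sample's label, and no column was left out. A symbol was found for 14572 of the 21153 identifiers and for 10833 of the 12444 genes tested. No reference genome was used, so genes are given without coordinates.

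Counts per library summed to between 21455021 and 32448438. At the lowest total, 1 CPM (the usual count scaled to library size) stands for about 21.5 counts. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count of 10, by group), and library sizes were scaled by TMM. Differences were tested with edgeR's quasi-likelihood test in a fit of all 12 libraries with the 4 group means as its terms, which share an estimate of the spread. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the 12444 genes tested, with a threshold of 0.05. The 7 comparisons were each treatment against control, the 3 pairs of treatments, and the interaction, which is the S100A4 effect in the presence of PDGF-BB minus that in its absence. Adjusted p-values in the text come from this test unless another is named, and n is 3 libraries per group throughout. Log2 CPM values for gene list tests, principal components and plots used a prior count of 2. R 4.3.3 was used.

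Replicates carried the numbers 1 to 3 in every group. The labels do not say that a number marks an animal. Deviations from the group means correlated at r = 0.746 to 0.908 across genes in the 18 pairs of libraries from different groups with the same number, and at −0.676 to 0.136 in the 36 pairs with different numbers. All 12 libraries correlated best with a library of their own number. The numbers were therefore taken as pairing the samples, from the data and not from the labels, before the calls of the fits were compared. The fit with replicate number as a block is given beside results where it changed the call or moved a count more than 1.5-fold. The common biological coefficient of variation was 27.2% without the block and 5.14% with it. Since no label ties the libraries to animals, p-values measure the spread between these libraries. Libraries of a group differed by more than sampling noise: chi-square per gene lay between 24.4 and 173, so none was counted as a repeat of another.

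The comparisons, the tests, the 25 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. For a comparison with control the rule took genes with a symbol, a mean of at least 1 log2 CPM, an adjusted p under the threshold and no overlap between the libraries of both groups, and of these the 10 largest changes in each direction. For the other comparisons it took the 5 largest. Where fewer than 3 genes qualified in a direction, the fit with the replicate block was used, with the same direction in all 3 same-numbered pairs in place of non-overlap, and after that the 3 smallest unadjusted p as values that did not pass. It also took up to 4 members of each list with the smallest adjusted p in each comparison with control. S100A4, AGER, TLR4, PDGFRA, PDGFRB, ACTA2, MYH11, TAGLN, CNN1 and SMTN were always looked at. Some genes that this rule took are not reported here. Of the 25 lists, 20 had at least 3 tested members. They were tested with camera of limma 3.58.1, with a preset correlation of 0.01, adjusted over 140 pairs of list and comparison. Camera with an estimated correlation and fry were run beside it. Of 29 calls by camera fry kept 19, and its values are given for some lists only.

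Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter and a stricter filter (at least 1 CPM in 3 libraries and a mean of 5 CPM), the groups compared alone, the replicate block, a test against a fold of 1.5, and leaving out each replicate number and each library in turn. Leaving out replicate numbers for the named genes and for the agreement between effects was chosen after seeing the data. For the effects with a shared control, unchanged groups and their controls were drawn from the means and spread of the fit with the block. A first version kept the measured controls and so left out their error; it was replaced after its values were seen. The fits were tested on simulated counts for the 12444 genes in which 200 genes changed by a known fold. For PDGF-BB against control, 35.8%, 44.8% and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 0 false calls among 108, and 80.6%, 83.6% and 97% with the block, with 19 false calls among 193. For S100A4 against control the shares were 41.8%, 62.7% and 81.8%, with 0 false calls among 124, and 89.6%, 95.5% and 98.5% with the block, with 15 among 204. For the interaction they were 11.9%, 38.8% and 65.2%, with 0 among 77, and 70.1%, 86.6% and 92.4% with the block, with 18 among 184. With the block the share of false calls was above the threshold for adjusted p in each of these comparisons.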

Results

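Gene expression was measured by RNA sequencing in smooth muscle cells cultured from porcine coronary artery and treated for 4 h with PDGF-BB, with S100A4, or with both. PDGF-BB is the homodimer of the platelet-derived growth factor B chain, a mitogen for smooth muscle cells. S100A4 is a calcium-binding protein that also acts outside cells. The design asks how each protein changes expression in these cells and whether their joint effect differs from the sum of the separate log2 effects. A sum on that scale is the product of the fold changes. Each of the 4 groups (control, PDGF-BB, S100A4 and PDGF-BB+S100A4) had 3 libraries, numbered 1 to 3, with 21455021 to 32448438 counts each. The genes with the highest mean were COL1A1 (29289 CPM), THBS1 (26814 CPM), COL1A2 (20619 CPM), FLNA (13736 CPM), FN1 (13550 CPM), COL3A1 (13335 CPM) and ACTA2, smooth muscle alpha-actin (12763 CPM).

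The 4 replicate 2 libraries stood apart from the other 8 on the first principal component, which held 49.9% of the variance. The second component held 20.6% and separated libraries with PDGF-BB from those without it. The third held 13.3% and separated replicate 1 (positive values) from replicate 3 (negative values) in every group. The fourth held 7.11% and separated libraries with S100A4 from those without it. Markers of other cell types differed with replicate number: PDGFRA, a receptor found on fibroblasts, averaged 138 CPM in replicate 2 and 22.8 CPM in the other replicates, and PECAM1, an endothelial adhesion molecule, 22.1 and 7.33 CPM. Since replicate numbers paired the libraries, results with replicate number as a block are given beside the fit on groups alone. In the text, values after a gene are log2 fold changes ± SE from the fit on groups alone, with n = 3 libraries per group, unless the block is named.

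**Figure D1:**
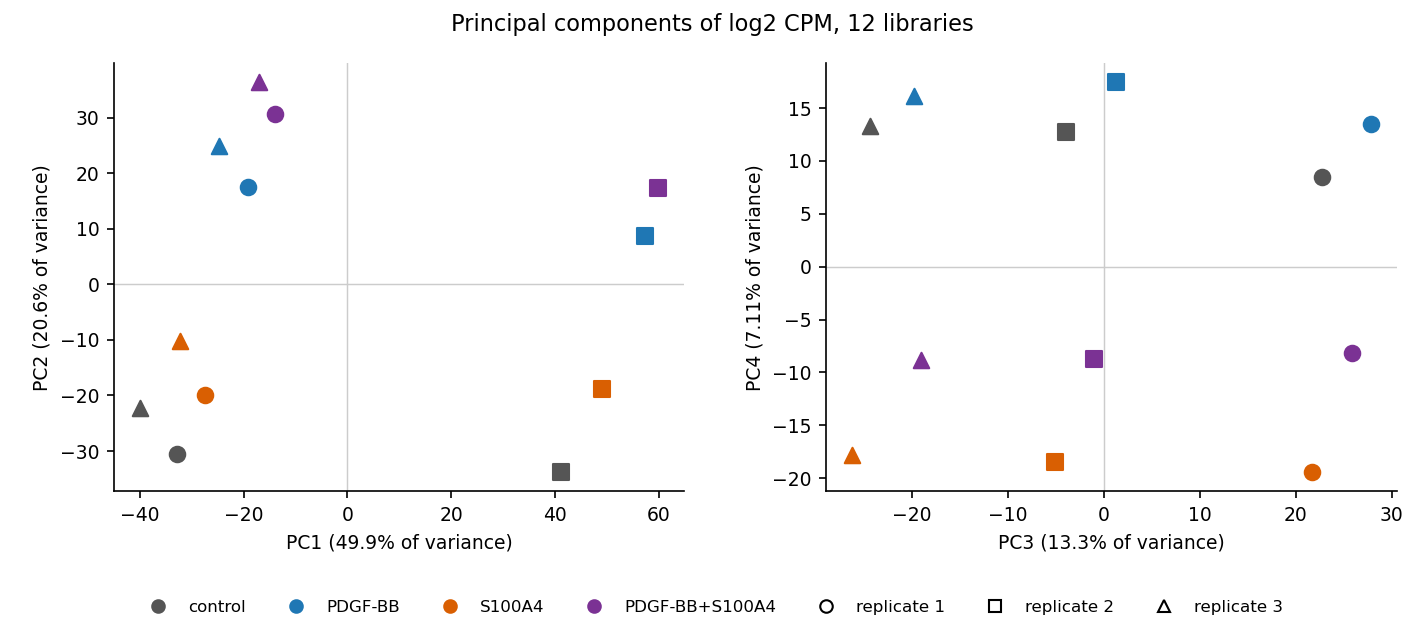
Principal components of log2 CPM over 12444 genes in 12 libraries, with each axis labelled by its share of variance, colour for the treatment and marker shape for the replicate number. Replicate 2 lies at 41.14 to 59.88 on PC1 and the other libraries at −40.01 to −13.89, while libraries with PDGF-BB have positive and libraries without it negative values on PC2.

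PDGF-BB against control gave the widest response of the single treatments. RGS4 (ENSSSCG00000006335), which ends G-protein signalling, rose 13.7-fold (3.77 ± 0.21, adjusted p = 4.1e-05). The cytokine LIF rose 12.4-fold (3.64 ± 0.65, adjusted p = 0.0047) and the early growth response factor EGR2 11.5-fold (3.52 ± 0.57, adjusted p = 0.0027). The semaphorin SEMA7A (3.44 ± 0.63), the ERK phosphatase DUSP5 (3.44 ± 0.46), the lysophospholipid transporter MFSD2A (3.41 ± 0.42), the EGF receptor inhibitor ERRFI1 (3.30 ± 0.30) and the collagen-binding integrin subunit ITGA2 (3.06 ± 0.33) also rose, with EVA1A (2.53 ± 0.18) and SH2D5 (2.49 ± 0.64). GHSR (ENSSSCG00000020906), the ghrelin receptor, fell most among the named genes (−3.14 ± 0.41, adjusted p = 0.00098), 8.8-fold lower than in control. It was followed by the transcription factor ATOH8 (−2.67 ± 0.34), the pro-apoptotic gene BMF (−2.60 ± 0.18), LURAP1L (−2.59 ± 0.17), the muscle ubiquitin ligase gene FBXO32 (−2.27 ± 0.19), the iron exporter SLC40A1 (−2.05 ± 0.41), the cyclin CCNG2 (−1.99 ± 0.29) and the transcription factor CEBPD (−1.96 ± 0.40). KANSL1L (−1.85 ± 0.14) and KLHL24 (−1.83 ± 0.25) completed the named genes that fell.

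Of 25 tested genes for making ribosomes, 20 rose with PDGF-BB and none fell (23 higher when adjusted over the list alone, 24 with the replicate block). Among them were PPAN (1.25 ± 0.10), RRS1 (1.31 ± 0.11), NOB1 (0.89 ± 0.08) and TSR1 (1.02 ± 0.09). The list's median log2 change was 0.71 (camera adjusted p = 2e-18, and adjusted p = 0.31 with an estimated correlation). Feedback targets of ERK signalling rose in 10 of 15 genes (11 when adjusted over the list alone, 14 with the block), including SPRY2 (2.03 ± 0.22), SPRED1 (1.16 ± 0.12), DUSP4 (1.30 ± 0.14) and the cyclin CCND1 (0.91 ± 0.09). Their median was 1.08 (camera adjusted p = 1.8e-10, and adjusted p = 0.31 with an estimated correlation). Of 20 immediate early factors, 10 rose and 1 fell (12 and 1 when adjusted over the list alone, 15 and 2 with the block). MYC (1.25 ± 0.13), MAFF (1.75 ± 0.20) and KLF10 (0.78 ± 0.10) rose, and the gene that fell was FOSL2 (−0.87 ± 0.11). The median was 0.68 (camera adjusted p = 1.6e-05, and adjusted p = 0.22 with an estimated correlation). By fry the adjusted p was 0.00035 for ribosome-making genes, 0.00041 for ERK feedback targets and 0.00035 for immediate early factors.

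Among inflammatory targets of NF-kB, 7 of 24 rose with PDGF-BB and 1 fell (9 and 1 when adjusted over the list alone, 13 and 5 with the block), with a median of 0.49 (camera adjusted p = 0.043, and adjusted p = 1 with an estimated correlation). ICAM1, a leukocyte adhesion molecule, rose by 0.91 ± 0.14, the NF-kB subunit RELB by 0.76 ± 0.09 and BIRC3 by 0.41 ± 0.08. Growth factor and cytokine genes rose in 3 of 19 and fell in 1 (8 and 1 when adjusted over the list alone, 12 and 3 with the block), with a median of 0.64 (camera adjusted p = 0.044, and adjusted p = 1 with an estimated correlation). HBEGF (2.31 ± 0.39), GDF15 (1.20 ± 0.26) and VEGFC (1.70 ± 0.38) rose, and the neurotrophin BDNF fell (−1.18 ± 0.19). Among proteases and their inhibitors 5 of 20 rose and 4 fell (5 and 4 when adjusted over the list alone, 9 and 6 with the block). This list was not called by camera (median 0.35, camera adjusted p = 0.34) but was by fry (adjusted p = 0.00065). By fry the adjusted p was 0.33 for NF-kB targets and 0.33 for growth factors and cytokines. Urokinase PLAU rose from 205 ± 47.1 CPM to 964 ± 43.4 CPM (mean ± SD, 2.23 ± 0.15, adjusted p = 4.8e-05), its receptor PLAUR by 1.47 ± 0.09, and the inhibitor SERPINE2 by 1.02 ± 0.13. In the glycolysis and hypoxia list, EGLN3 (2.15 ± 0.30), VEGFA (1.75 ± 0.28) and the hexokinase HK2 (1.14 ± 0.20) rose, while the list was not called (3 higher and 2 lower when adjusted over the list alone, 9 and 3 with the block; median 0.10, camera adjusted p = 0.33).

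Of 23 contractile genes, 1 rose with PDGF-BB (SRF, 0.54 ± 0.11) and 1 fell (SMTN, smoothelin, −0.69 ± 0.14), and the list was called only with the replicate block, with 3 members higher and 13 lower (median −0.17, camera adjusted p = 0.51, block 0.04, and adjusted p = 0.84 with the block and an estimated correlation). The values of ACTA2 (−0.02 ± 0.48), CNN1 (−0.06 ± 0.50) and MYH11, smooth muscle myosin (−0.44 ± 0.77), did not pass. MYH11 fell with the block (−0.51 ± 0.07, adjusted p = 4.6e-05). TAGLN, often abundant in smooth muscle, had 83 to 213 counts per library and is uncertain here (0.06 ± 0.35). Interferon-response genes did not pass in any of 19 members, and with the block 12 were lower (median −0.71, camera adjusted p = 0.23, block 0.0036, and adjusted p = 0.80 with the block and an estimated correlation). The same held for G2/M genes, with 10 of 18 lower under the block (median −0.18, camera adjusted p = 0.80, block 0.024, and adjusted p = 0.84 with the block and an estimated correlation). These 3 lists also differed with replicate number: in control cells their medians in replicate 2 minus the mean of replicates 1 and 3 were −0.66, −2.37 and 1.24. S100A10 rose (0.28 ± 0.07), whereas S100A4 itself (−0.18 ± 0.35, block adjusted p = 0.03), PDGFRA (−0.21 ± 1.28, block adjusted p = 0.16) and PDGFRB (−0.06 ± 0.42, block adjusted p = 0.2) did not pass without the block, and the last 2 did not pass with it. The endothelial list was not called (1 of 7 higher, 3 with the block, camera adjusted p = 0.86), but its member ERG rose (1.23 ± 0.30, adjusted p = 0.022).

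The remaining lists were not called with PDGF-BB. Of 24 matrix genes none passed (block 7 higher and 8 lower, median −0.03, camera adjusted p = 0.86). Among 21 sterol synthesis genes HSD17B7 (0.75 ± 0.20) rose and INSIG1 (−0.74 ± 0.18) fell (block 9 higher and 4 lower, median 0.11, camera adjusted p = 0.64). TGF-beta and YAP targets had 1 of 19 members higher, SKI (0.29 ± 0.06), and 4 lower, including SMAD6 (−1.58 ± 0.19) and ID3 (−0.55 ± 0.11), with a median of −0.12 (block 6 higher and 9 lower, camera adjusted p = 0.55). Of 17 genes of the unfolded protein and amino acid stress responses, HSPA5 (0.55 ± 0.15) and HSP90B1 (0.26 ± 0.06) rose (block 6 higher and 7 lower), and the list's median (−0.08) and test differed in sign (camera adjusted p = 0.92). No member passed among 16 G1/S genes (block 2 higher and 2 lower, camera adjusted p = 0.97), 9 fibroblast markers (block 2 and 2, 0.95), 5 macrophage markers (block 0 and 1, 0.95) or 5 pericyte markers (block 1 and 2, 0.77). A list of S100 proteins, PDGF chains, PDGF receptors, TLR4 and its adaptor MYD88 had 1 of 13 members past the threshold (block 3 higher and 5 lower, camera adjusted p = 0.97). Markers of T cells, cardiomyocytes and Schwann cells had 1 tested gene each, and epithelial markers and mitochondrially encoded genes had 0, so these 5 lists were not tested.

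In total PDGF-BB changed 1830 of 12444 genes, 1131 higher and 699 lower, and 6075 with the replicate block, 3029 higher and 3046 lower. All 1830 kept their direction and passed with the block. Upper-quartile scaling gave 1907 genes, of which 49% were higher in place of 61.8%. The count fell to 131 without replicate 1 and 377 without replicate 3 of all groups, to 1119 and 1167 without control replicates 1 and 3, and to 1209 without PDGF-BB replicate 1. The fit with the block gave 4372 and 4446 genes without replicates 1 and 3 of all groups. Both groups were without overlap for 29.8% of tested genes. Chance gives 10% if libraries are unpaired, and since same-numbered libraries vary together here, that value is no measure of chance for any of these comparisons.

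**Figure D2:**
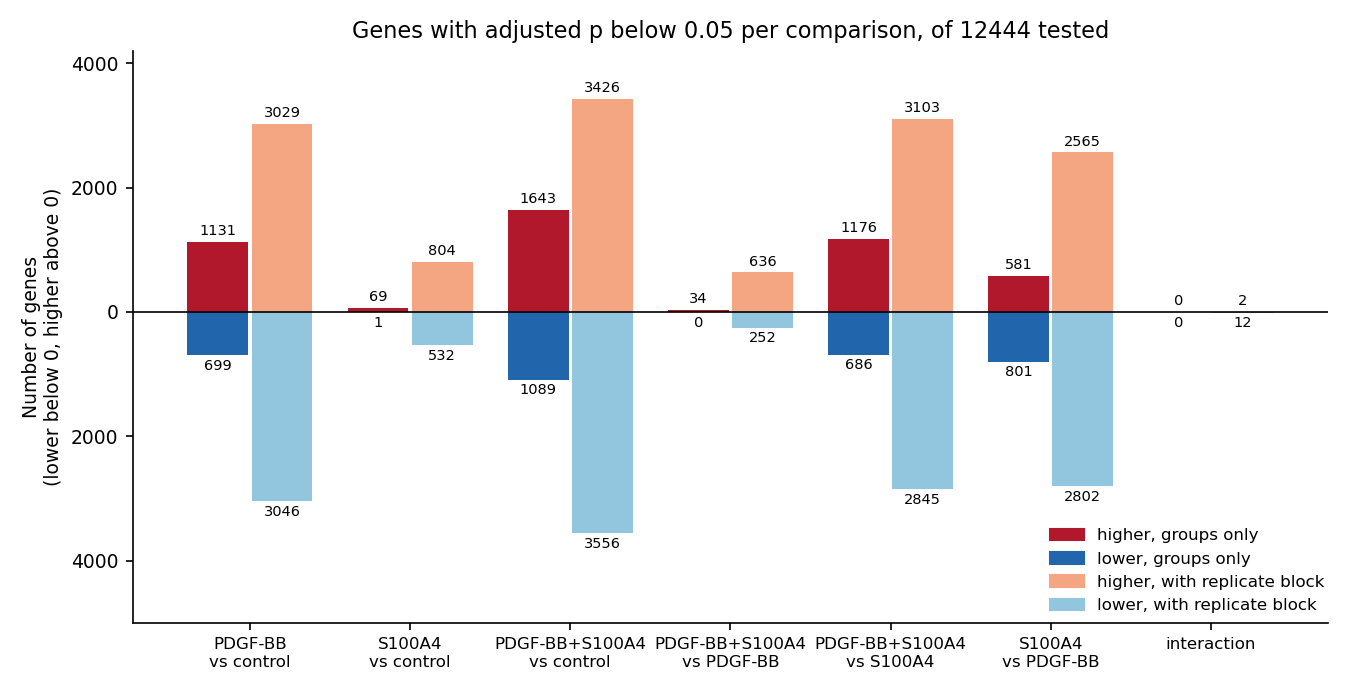
Number of genes with an adjusted p below 0.05 in each comparison, higher above 0 and lower below 0, from the fit on groups alone (dark) and with the replicate block (light). PDGF-BB changed 1830 genes and S100A4 70 on groups alone, and 6075 and 1336 with the block.

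S100A4 against control raised more genes than it lowered. RND1 (ENSSSCG00000038562) rose 27.3-fold (4.77 ± 0.43, adjusted p = 0.00084) and the steroid reductase AKR1D1 19.4-fold (4.28 ± 0.58, adjusted p = 0.0081). The adhesion molecules VCAM1 (3.69 ± 0.55, adjusted p = 0.014), ICAM4 (3.43 ± 0.25) and ICAM1 (2.22 ± 0.15) rose 12.9-fold, 10.8-fold and 4.64-fold. TNFAIP3, which restrains NF-kB, rose 6.99-fold (2.81 ± 0.27), the hyaluronan-binding TNFAIP6 6.37-fold (2.67 ± 0.37), the aggrecanase ADAMTS4 6.25-fold (2.64 ± 0.34), TLR2 4.71-fold (2.24 ± 0.35) and USP54 4.27-fold (2.09 ± 0.17). LURAP1L (ENSSSCG00000036360) was the only gene that fell on groups alone in edgeR (−1.10 ± 0.16, adjusted p = 0.015). With the block TOX (−0.93 ± 0.11), ATOH8 (−0.87 ± 0.17), the muscle ubiquitin ligase gene TRIM63 (−0.85 ± 0.12) and EPHA7 (−0.80 ± 0.12) fell as well, as did NKD1 (−0.78 ± 0.10), TANC2 (−0.74 ± 0.13), HAND2 (−0.74 ± 0.13) and TRIM9 (−0.73 ± 0.22).

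Of 24 NF-kB targets tested, 10 rose with S100A4 and none fell, and 23 rose when adjusted over the list alone or with the replicate block. Their median log2 change was 1.99 (camera adjusted p = 6.4e-50, and adjusted p = 0.06 with an estimated correlation). RELB (1.44 ± 0.09) and the inhibitor NFKBIA (1.96 ± 0.15) were among them, and NFKBIA went from 37.5 ± 6.17 CPM to 146 ± 15.6 CPM (mean ± SD). CXCL8, chosen after its values were seen, did not pass on groups alone (4.57 ± 1.58, adjusted p = 0.5) and rose with the block (4.51 ± 0.36, adjusted p = 1.2e-06). By fry the adjusted p was 0.00035 for NF-kB targets and 0.0054 for proteases and inhibitors. It was 0.26 for immediate early factors and 0.73 for growth factors and cytokines. Among 20 proteases and inhibitors 2 rose, ADAMTS4 and PLAU (0.91 ± 0.14), and none fell (4 when adjusted over the list alone, block 6 higher and 2 lower; median 0.17, camera adjusted p = 0.00048, and adjusted p = 0.088 with an estimated correlation). Of 20 immediate early factors MAFF alone rose (1.09 ± 0.20, adjusted p = 0.045), and 1 was called when adjusted over the list alone (block 6 higher and 2 lower; median 0.25, camera adjusted p = 0.015, and adjusted p = 0.39 with an estimated correlation). PTHLH (ENSSSCG00000036893), parathyroid hormone-like hormone, rose from 9.44 ± 2.00 CPM to 37.6 ± 9.92 CPM (1.99 ± 0.30, adjusted p = 0.015) and was the only one of 19 growth factor and cytokine genes to pass, also when adjusted over the list alone (block 9 higher and 2 lower; median 0.37, camera adjusted p = 0.02, and adjusted p = 1 with an estimated correlation).

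ERK feedback targets and ribosome-making genes were called as lists although 0 of 15 and 0 of 25 members passed with S100A4 (0 and 1 when adjusted over the list alone). Their medians were 0.26 and 0.11 (camera adjusted p = 6e-05 and 3.7e-06, adjusted p = 0.67 and 0.95 with an estimated correlation, and 0.4 and 0.5 by fry). With the block 6 ERK targets rose, such as IER3 (1.64 ± 0.11), and 1 fell, and 6 ribosome-making genes rose, such as RRS1 (0.55 ± 0.08). Contractile genes were called lower only with the block, where 9 of 23 fell and none rose, among them SMTN (−0.45 ± 0.05), TPM1 (−0.15 ± 0.04) and ACTA2 (−0.18 ± 0.05; median −0.14, camera adjusted p = 0.12, block 5.3e-05, and adjusted p = 0.72 with the block and an estimated correlation). Genes responding to TGF-beta or YAP were likewise called lower only with the block, with 6 of 19 lower and 1 higher, among them AJUBA (−0.59 ± 0.07) and SMAD6 (−0.43 ± 0.08; median −0.08, camera adjusted p = 0.12, block 0.021, and adjusted p = 0.50 with the block and an estimated correlation). Interferon-response genes were not called (block 2 higher and 4 lower of 19, median −0.29, camera adjusted p = 0.97). Of the possible receptors for extracellular S100A4, AGER and TLR4 were looked at. AGER was near the limit of detection, with 0 to 4 counts per library, and was not tested. TLR4 was detected, at 8.04 CPM in control, and its change did not pass (0.11 ± 1.04).

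In total S100A4 changed 70 genes, 69 higher and 1 lower, and 1336 with the replicate block, 804 higher and 532 lower. All 70 passed with the block in the same direction. Values of S100A4 and control were without overlap for 9.72% of tested genes (10% by chance if unpaired), which decides nothing on an effect, because the spread between replicate numbers is shared by both groups. DESeq2 called 199. In edgeR 0 passed without replicate 3 of all groups (491 at an unadjusted p under 0.05) and 1 without replicate 1. The count was 36 without control replicate 1 and 40 without control replicate 3. With the block it was 612 without replicate 1, 608 without replicate 3, 827 without control replicate 3, and 863 and 697 without S100A4 replicates 1 and 2.

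**Figure D3:**
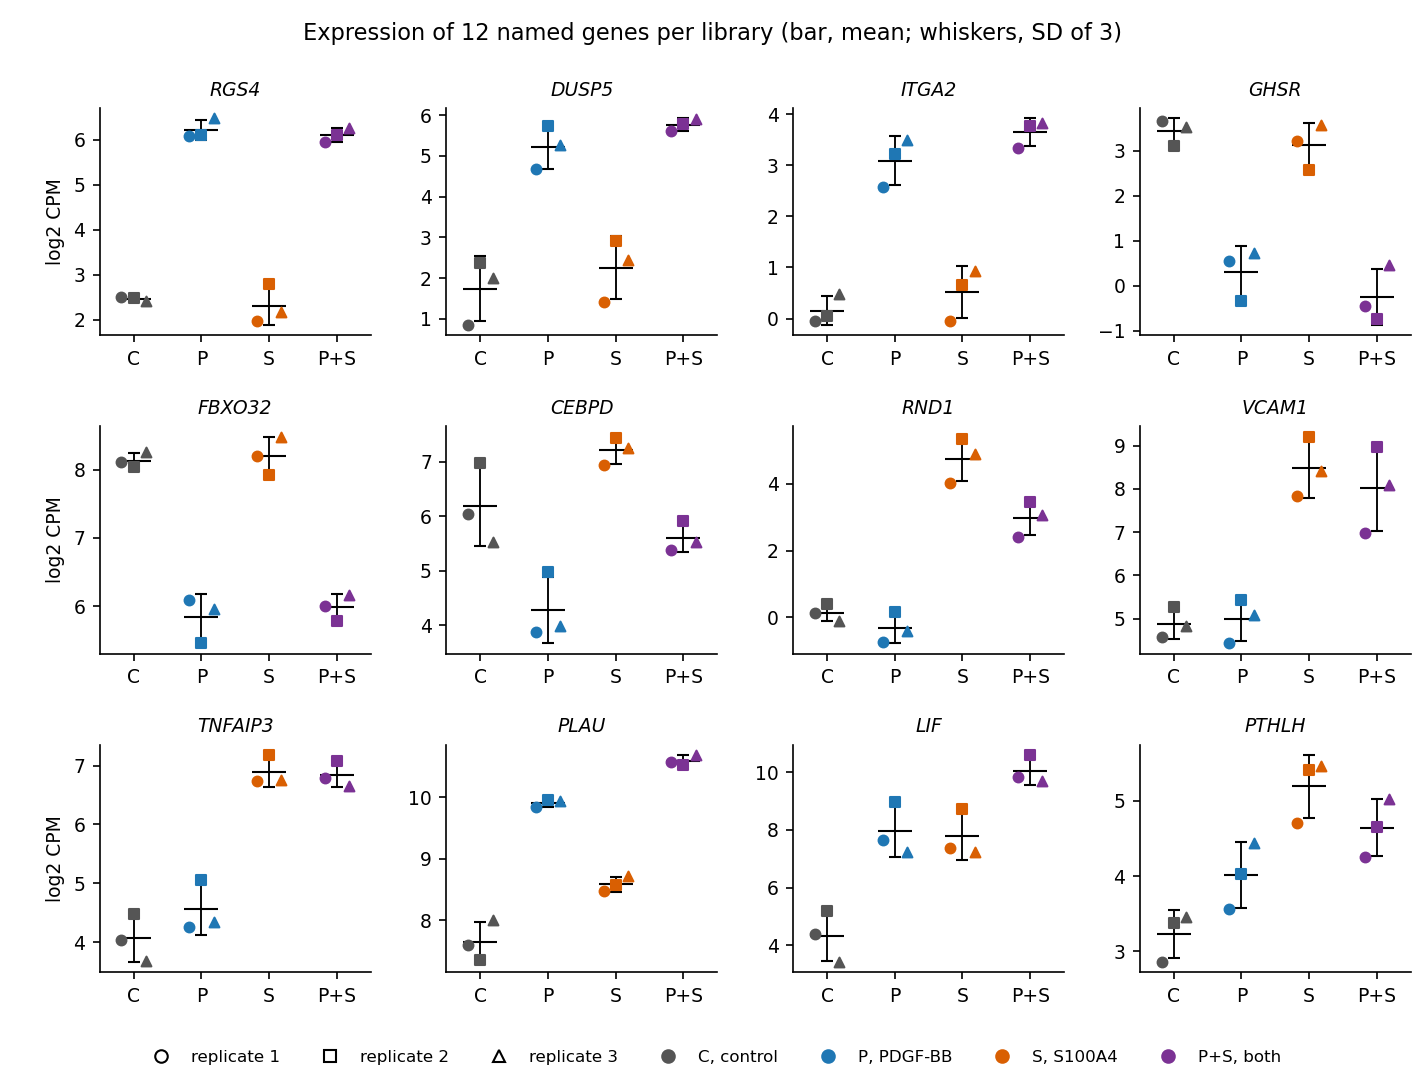
Log2 CPM of 12 named genes in each library, with control (C), PDGF-BB (P), S100A4 (S) and both proteins (P+S) on the horizontal axis, marker shape for the replicate number, a bar for the mean and whiskers for the SD of 3 libraries. RGS4, DUSP5 and ITGA2 are higher and GHSR and FBXO32 lower in every library with PDGF-BB, and RND1, VCAM1 and TNFAIP3 are higher in every library with S100A4.

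The combination against control gave the largest number of changed genes of the 7 comparisons. The chemokine gene AMCF-II (ENSSSCG00000008957) rose 134-fold (7.06 ± 1.4, adjusted p = 0.0054), LIF 47.8-fold (5.58 ± 0.71, adjusted p = 0.00047), the neutrophil chemokine CXCL8 46.9-fold (5.55 ± 1.65, adjusted p = 0.037) and CXCL2 19.9-fold (4.31 ± 1.25, adjusted p = 0.034). Counts of these related chemokines are uncertain, since the treatment of reads with several matches is not given. The rise of CXCL8 and CXCL2 was smallest in replicate 2, where control values were highest. In replicates 1, 2 and 3 CXCL8 had 0.32, 4.9 and 1.17 log2 CPM in control, and 7.93, 9.93 and 8.48 with both proteins. CXCL2 had 1.29, 4.51 and 0.83 in control, and 6.61, 8.27 and 7.07 with both. MFSD2A (4.47 ± 0.44), ICAM4 (4.11 ± 0.25), DUSP5 (3.92 ± 0.47), the cytokine IL1A (3.88 ± 0.98), EGR2 (3.75 ± 0.58) and ERRFI1 (3.74 ± 0.31) were the other leading genes. GHSR fell 13.1-fold (−3.71 ± 0.43, adjusted p = 0.00028). It was followed by ATOH8 (−3.37 ± 0.36), LURAP1L (−3.31 ± 0.18), BMF (−2.68 ± 0.18), SLC40A1 (−2.53 ± 0.42), TRIM63 (−2.38 ± 0.17), FBXO32 (−2.14 ± 0.19), the thrombopoietin gene THPO (−2.13 ± 0.68, adjusted p = 0.049) and RALGPS2 (−2.09 ± 0.23).

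NF-kB targets rose in 19 of 24 genes with the combination (20 when adjusted over the list alone, 22 with the block), with a median of 2.04 (camera adjusted p = 4.9e-12, and adjusted p = 0.32 with an estimated correlation). Ribosome-making genes rose in 23 of 25 (24 when adjusted over the list alone, 25 with the block; median 0.83, camera adjusted p = 7.7e-17, and adjusted p = 0.31 with an estimated correlation). ERK feedback targets rose in 12 of 15 (14 when adjusted over the list alone, 14 with the block; median 1.21, camera adjusted p = 1.5e-09, and adjusted p = 0.31 with an estimated correlation). Immediate early factors rose in 12 of 20 and fell in 1, again FOSL2 (14 and 1 when adjusted over the list alone, 15 and 3 with the block; median 1.03, camera adjusted p = 3.4e-05, and adjusted p = 0.22 with an estimated correlation). Of 19 growth factor and cytokine genes, 9 rose, among them HBEGF (3.17 ± 0.40), and 1 fell, BDNF (−1.81 ± 0.20; 9 and 1 when adjusted over the list alone, 13 and 3 with the block; median 1.32, camera adjusted p = 0.032, and adjusted p = 1 with an estimated correlation). Of 20 proteases and inhibitors 5 rose and 1 fell (6 and 2 when adjusted over the list alone, 12 and 4 with the block; median 0.71, camera adjusted p = 0.02, and adjusted p = 0.23 with an estimated correlation). PLAU reached 1548 ± 92.9 CPM (mean ± SD, 2.92 ± 0.15, adjusted p = 8e-06), PLAUR rose by 1.78 ± 0.10 and ADAMTS4 by 3.15 ± 0.34.

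In the contractile list SMTN (−0.83 ± 0.14), TPM1 (−0.31 ± 0.08) and MYLK, myosin light chain kinase (−0.52 ± 0.16), fell and SRF rose (0.52 ± 0.11), while ACTA2 (−0.09 ± 0.48) and CNN1 (−0.03 ± 0.50) did not pass. With the block 4 of the 23 contractile genes were higher and 12 lower, and the list was not called (median −0.27, camera adjusted p = 0.39, block 0.051). Hyaluronan synthase HAS2 (3.36 ± 1.05, adjusted p = 0.044) and osteopontin SPP1 (1.39 ± 0.23) rose among 24 matrix genes and LOX (−0.36 ± 0.08) and COL3A1 (−0.30 ± 0.09) fell, and the list as a whole was not called (block 8 higher and 10 lower, camera adjusted p = 0.92). Called only with the block were interferon-response genes (1 higher and 13 lower of 19, median −0.56, camera adjusted p = 0.34, block 0.012), G2/M genes (11 lower of 18, median −0.27, camera adjusted p = 0.77, block 0.03), and glycolysis and hypoxia genes (12 higher and 3 lower of 18, median 0.20, camera adjusted p = 0.20, block 0.04), and none of the 3 held with the block and an estimated correlation (adjusted p = 0.81, 0.84 and 0.76). The unfolded protein response chaperone HSPA5 rose (0.81 ± 0.15), in a list that was not called (3 of 17 higher, block 7 higher and 6 lower). SMAD6, an inhibitor of BMP signalling, fell (−2.05 ± 0.20) in the list of TGF-beta and YAP targets, which was not called (1 higher and 5 lower of 19, block 7 and 11). In the fibroblast list TCF21 rose (1.46 ± 0.30), and in the endothelial list ERG (1.27 ± 0.30), with neither list called (block 3 higher and 3 lower of 9 fibroblast markers and 1 higher of 7 endothelial markers).

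In total the combination changed 2732 genes, 1643 higher and 1089 lower, and 6982 with the replicate block, 3426 higher and 3556 lower. All 2732 passed with the block in the same direction. Upper-quartile scaling gave 2830 genes, with 46.1% higher in place of 60.1%. The groups were without overlap for 35.6% of tested genes (10% by chance if unpaired). The count was 502 without replicate 1 and 991 without replicate 3 of all groups, and 5312 and 5437 with the block.

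**Figure D4:**
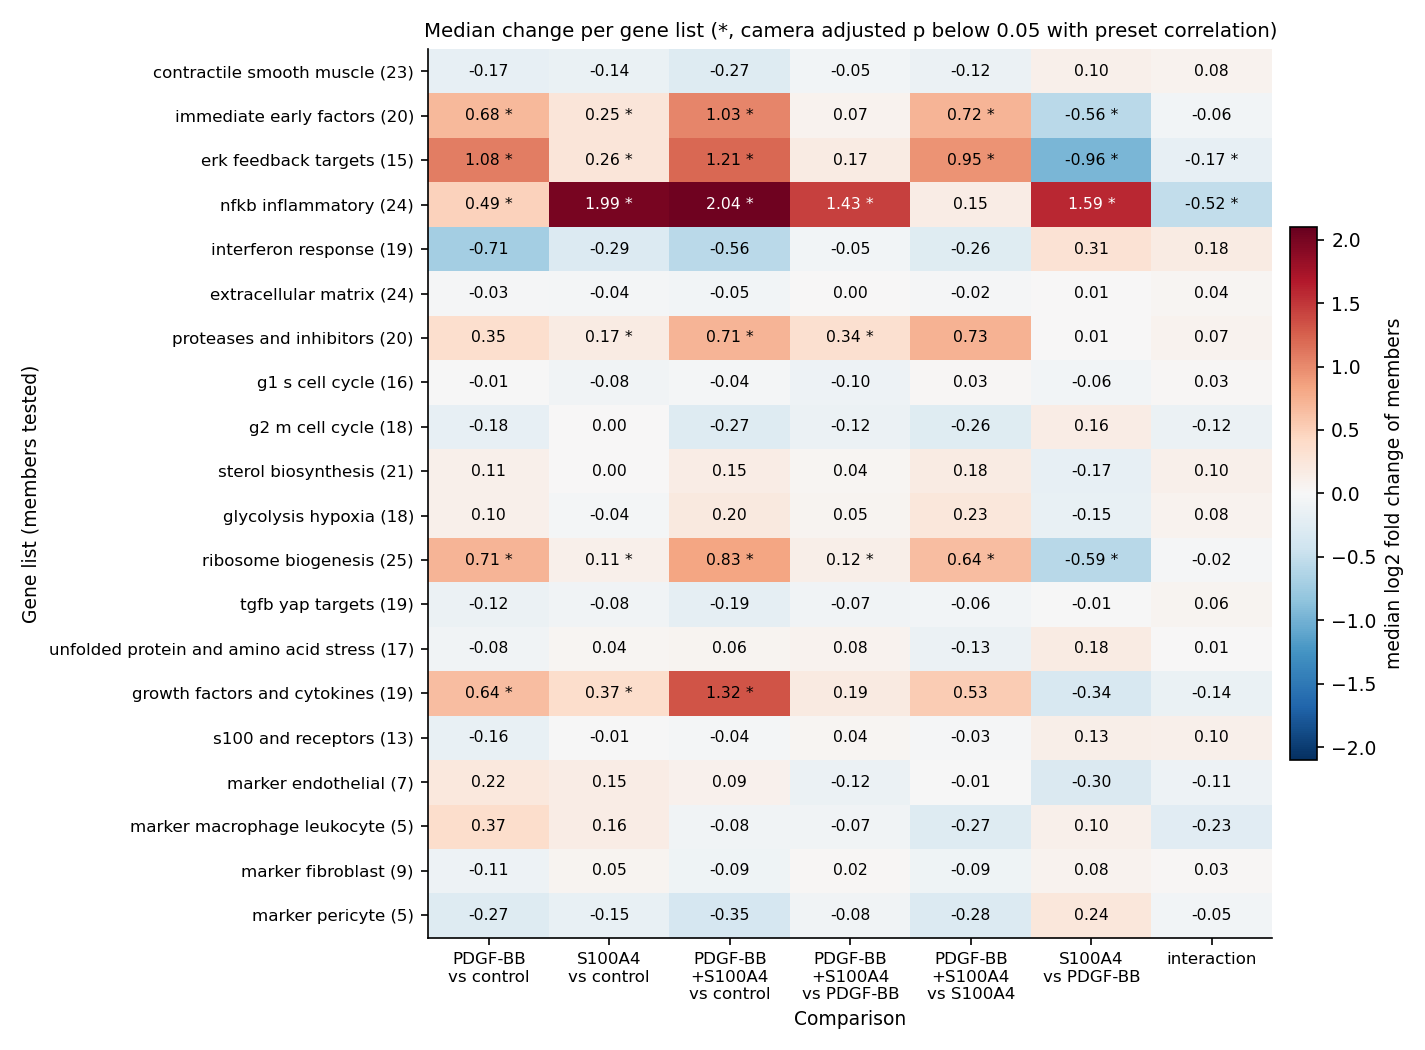
Median log2 fold change of the tested members of 20 gene lists (vertical axis, number tested in brackets) in 7 comparisons (horizontal axis), with a star where camera with the preset correlation gave an adjusted p below 0.05. NF-kB targets have medians of 1.99 and 1.43 for S100A4 without and with PDGF-BB, and ribosome-making genes 0.71 and 0.64 for PDGF-BB without and with S100A4.

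Adding S100A4 to PDGF-BB raised 34 genes, of which 30 had also risen with S100A4 alone. Against PDGF-BB alone, RND1 rose 10.8-fold (3.43 ± 0.42, adjusted p = 0.007), VCAM1 9.16-fold (3.20 ± 0.53, adjusted p = 0.0499, DESeq2 2.4e-08, block 3.2e-08), ICAM4 5-fold (2.32 ± 0.23), TNFAIP3 4.77-fold (2.25 ± 0.26) and NFKBIA 3.48-fold (1.8 ± 0.15). The call of VCAM1 was lost under upper-quartile scaling (adjusted p = 0.057) and without replicate 1, 2 or 3 of all groups (adjusted p = 0.37, 0.087 and 1). NF-kB targets rose in 7 of 24 genes and fell in none (19 when adjusted over the list alone, 24 with the block), with a median of 1.43 (camera adjusted p = 3.4e-43, and adjusted p = 0.064 with an estimated correlation). Proteases and inhibitors had 1 of 20 members higher (4 when adjusted over the list alone, 10 with the block; median 0.34, camera adjusted p = 5e-07), and this was the only one of 29 calls over the 7 comparisons that held with an estimated correlation (adjusted p = 0.048). With the block and an estimated correlation 0 of 140 pairs of list and comparison passed. Ribosome-making genes were called with a median of 0.12 and no member past the threshold, with or without the block or when adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 1 with an estimated correlation). With the block ERK feedback targets (median 0.17, camera adjusted p = 0.16, block 0.048) and growth factors (median 0.19, camera adjusted p = 0.25, block 0.041) were called as well, with 3 higher and 1 lower of 15 and 7 higher and 2 lower of 19, but not with the block and an estimated correlation (adjusted p = 0.80 and 0.66). No gene fell in the fit on groups alone by edgeR (0 lower, against 6 by DESeq2). With the block PLEKHA6 (−0.93 ± 0.12), HEPACAM (−0.92 ± 0.23), HAND2 (−0.82 ± 0.14) and TRIM63 (−0.76 ± 0.16) fell. HEPACAM fell mostly in replicate 2. In replicates 1, 2 and 3 it had 6.58, 7.04 and 6.98 log2 CPM with PDGF-BB, and 6.24, 4.93 and 6.5 with both proteins.

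In total 34 genes were higher with the combination than with PDGF-BB and 0 lower, and the groups were without overlap for 8.69% of tested genes (10% by chance if unpaired), which likewise decides nothing. With the replicate block 636 were higher and 252 lower, 888 together, including all 34. DESeq2 called 118 genes on groups alone. At an unadjusted p under 0.05 there were 599. The edgeR count was 0 without replicate 3 of all groups (332 at an unadjusted p under 0.05) and 1 without replicate 1. It was 8, 19 and 12 without PDGF-BB replicates 1, 2 and 3, and 20 without PDGF-BB+S100A4 replicate 3. With the block it was 379 without replicate 1, 326 without replicate 3 and 508 without PDGF-BB+S100A4 replicate 3.

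Adding PDGF-BB to S100A4 raised 1176 genes, of which 918 had also risen with PDGF-BB alone, and lowered 686, of which 478 had also fallen with it. RGS4 (3.76 ± 0.21, adjusted p = 4.3e-05), DUSP5 (3.40 ± 0.46), ITGA2 (3.15 ± 0.32), ERRFI1 (3.10 ± 0.30) and SEMA7A (2.98 ± 0.61) rose, and GHSR (−3.44 ± 0.43), ATOH8 (−2.51 ± 0.35), BMF (−2.33 ± 0.18), FBXO32 (−2.23 ± 0.19) and LURAP1L (−2.21 ± 0.18) fell. Ribosome-making genes rose in 21 of 25 (24 when adjusted over the list alone, 24 with the block; median 0.64, camera adjusted p = 4.2e-17, and adjusted p = 0.31 with an estimated correlation), and ERK feedback targets in 11 of 15 (11 when adjusted over the list alone, 12 with the block; median 0.95, camera adjusted p = 4.4e-08, and adjusted p = 0.35 with an estimated correlation). Immediate early factors rose in 10 of 20 and fell in 1 (11 and 1 when adjusted over the list alone, 14 and 3 with the block; median 0.72, camera adjusted p = 0.00011, and adjusted p = 0.23 with an estimated correlation). Lists called only with the block were interferon-response genes (10 of 19 lower, camera adjusted p = 0.26, block 0.0074), G2/M genes (10 of 18 lower, camera adjusted p = 0.77, block 0.037) and glycolysis and hypoxia genes (12 higher and 3 lower of 18, camera adjusted p = 0.096, block 0.013), and none of the 3 held with the block and an estimated correlation (adjusted p = 0.80, 0.84 and 0.72). In total 1862 genes changed, 1176 higher and 686 lower, and 5948 with the block, 3103 higher and 2845 lower. All 1862 passed with the block in the same direction. Upper-quartile scaling gave 1897 genes with 49.9% higher in place of 63.2%. The groups were without overlap for 30% of tested genes (10% by chance if unpaired). The count was 10 without replicate 1 and 274 without replicate 3 of all groups, 1139 without PDGF-BB+S100A4 replicate 1, and 1032 and 1150 without S100A4 replicates 1 and 3. The fit with the block gave 4009 and 4241 genes without replicates 1 and 3 of all groups.

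Between the single treatments, RND1 (5.24 ± 0.44, adjusted p = 0.00017), AKR1D1 (4.68 ± 0.59), VCAM1 (3.56 ± 0.54), IL1A (3.41 ± 0.95) and podoplanin PDPN (3.39 ± 0.72) were higher with S100A4, and RGS4 (−3.88 ± 0.21, adjusted p = 6.7e-05), DUSP5 (−2.92 ± 0.45), SEMA7A (−2.72 ± 0.60), ERRFI1 (−2.66 ± 0.30) and ITGA2 (−2.63 ± 0.32) lower. NF-kB targets were higher with S100A4 in 12 of 24 genes (13 when adjusted over the list alone, block 21 higher and 1 lower; median 1.59, camera adjusted p = 6.8e-12, and adjusted p = 0.32 with an estimated correlation). Ribosome-making genes were lower in 18 of 25 (23 when adjusted over the list alone, 24 with the block; median −0.59, camera adjusted p = 1.1e-16, and adjusted p = 0.31 with an estimated correlation) and ERK feedback targets in 10 of 15 (10 when adjusted over the list alone, block 11 lower and 2 higher; median −0.96, camera adjusted p = 4.4e-07, and adjusted p = 0.39 with an estimated correlation). Immediate early factors were lower in 8 of 20 and higher in 1 (11 and 1 when adjusted over the list alone, 12 and 4 with the block; median −0.56, camera adjusted p = 0.00043, and adjusted p = 0.29 with an estimated correlation). Called only with the block were interferon-response genes (8 of 19 higher, camera adjusted p = 0.21, block 0.0087), G2/M genes (10 of 18 higher, camera adjusted p = 0.83, block 0.04) and glycolysis and hypoxia genes (3 higher and 11 lower of 18, camera adjusted p = 0.24, block 0.048), and none of the 3 held with the block and an estimated correlation (adjusted p = 0.80, 0.84 and 0.79). In total 1382 genes differed, 581 higher and 801 lower with S100A4, and 5367 with the block, 2565 higher and 2802 lower. All 1382 passed with the block in the same direction, and the groups were without overlap for 26.4% of tested genes (10% by chance if unpaired). The count was 5 without replicate 1 and 176 without replicate 3 of all groups, 877 without PDGF-BB replicate 1, and 769 and 850 without S100A4 replicates 1 and 3. The fit with the block gave 3628 and 3742 genes without replicates 1 and 3 of all groups.

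The interaction asks whether the S100A4 effect differed in the presence of PDGF-BB. No gene passed on groups alone with edgeR, DESeq2 or limma-voom (0 each), and 152 had an unadjusted p under 0.05 with edgeR. Among named genes, TM4SF1 (0.60 ± 0.14), TSPAN2 (2.85 ± 0.76) and KDM6B (0.51 ± 0.14) had the smallest unadjusted p with a positive value and did not pass (adjusted p = 1 for each). TSPAN2 lay near the floor, at −3.18 to −0.74 log2 CPM over all libraries. With the replicate block 14 genes passed, 2 with a positive and 12 with a negative value. PTHLH had the largest among the named genes (−1.35 ± 0.11, adjusted p = 0.00014): S100A4 raised it by 1.98 without PDGF-BB and by 0.63 with it. LIF (−1.31 ± 0.20), the bradykinin receptor BDKRB2 (−1.08 ± 0.15), the pro-apoptotic gene PMAIP1 (−1 ± 0.17) and the ubiquitin ligase gene NEDD4L (−0.77 ± 0.12) also had negative values, and TM4SF1 (0.60 ± 0.09) and IGFBP5 (0.43 ± 0.07) positive ones. NF-kB targets as a list had a median interaction of −0.52 (camera adjusted p = 1.8e-07, and adjusted p = 0.58 with an estimated correlation), with 0 of 24 members past the threshold (1 lower when adjusted over the list alone, 2 lower with the block). ERK feedback targets had a median of −0.17 (camera adjusted p = 0.018, and adjusted p = 1 with an estimated correlation), with no member past the threshold, also when adjusted over the list alone. Contractile genes (median 0.08, camera adjusted p = 0.46, block 0.0032) and glycolysis and hypoxia genes (median 0.08, camera adjusted p = 0.38, block 0.04) were called only with the block, and not with the block and an estimated correlation (adjusted p = 0.81 and 0.76). The count of 14 was 1 without replicate 1, 117 without replicate 2 and 2 without replicate 3. Without single libraries it was 32 and 2 (control replicates 2 and 3), 1 and 4 (PDGF-BB replicates 1 and 3), 1 and 2 (S100A4 replicates 1 and 3) and 9, 35 and 3 (PDGF-BB+S100A4 replicates 1, 2 and 3). DESeq2 with the block called 58 genes, and 1183 had an unadjusted p under 0.05 with edgeR and the block.

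The S100A4 effect without PDGF-BB and that with it rest on separate libraries. Across 12444 genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.677 and a Spearman coefficient of 0.434. Of 69 genes higher without PDGF-BB and 34 higher with it, 30 were shared, against 0.2 for independent lists, among them TNFAIP3, NFKB1, NFKB2, NFKBIE, IRAK2, MAP3K8 and STAT5A. All 69 had a positive value with PDGF-BB, with a median of 0.83 against 1.22 without it. The 69 were chosen by their call without PDGF-BB, which favours high values there, so the lower median alone does not show a weaker effect. The PDGF-BB effect without and with S100A4 correlated at r = 0.844 (Spearman coefficient 0.816), and 918 of 1131 and 1176 higher genes and 478 of 699 and 686 lower genes were shared, against 106.9 and 38.5. Restricting the genes to a mean of at least 3 log2 CPM (8659 genes) gave r = 0.837 and 0.934. Of the 804 and 636 higher genes with the block, 445 were shared (41.1 for independent lists), and of the 532 and 252 lower genes 109 (10.8).

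**Figure D5:**
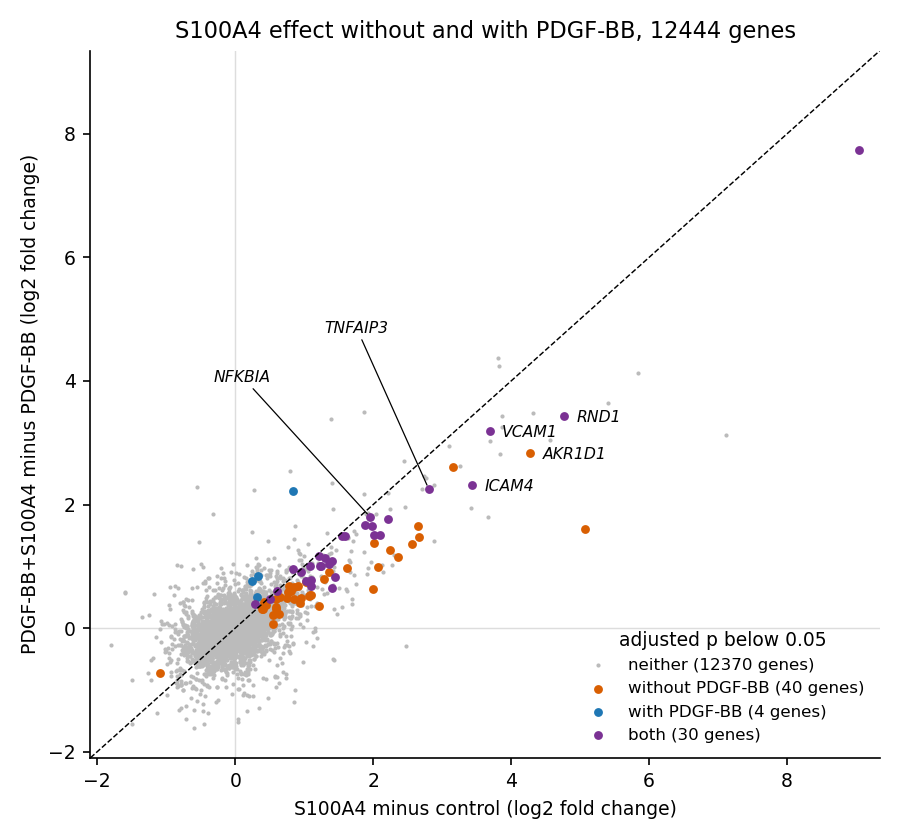
Log2 fold change of S100A4 against control (horizontal axis) and of PDGF-BB+S100A4 against PDGF-BB (vertical axis) for 12444 genes, with colour for an adjusted p below 0.05 and a dashed line where both are equal. Of the called genes, 30 were called in both comparisons, and the 69 genes higher without PDGF-BB lie above 0 on both axes.

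PDGF-BB and S100A4 were compared with the same control libraries, which makes their fold changes correlate with no effect at all. The observed correlation was r = 0.392 on log2 CPM, below the mean of 0.514 (highest 0.543) of 100 simulated pairs of unchanged groups with a shared control. Effects of a single protein widen the changes and lower r, so r decides nothing for or against a shared response. The covariance was 0.0561 against a simulated mean of 0.011 (highest 0.0122), a difference of 0.0451, with the spread of the fit with the block in the simulation. On groups alone 31 genes were higher with both proteins (6.3 for independent lists), among them ICAM1, ICAM4, PLAU, ADAMTS4 and MAFF, and LURAP1L was lower with both. With the block 425 genes were higher (195.7) and 381 lower (130.2) with both. Simulated unchanged groups, tested in edgeR with the block, gave at most 4 calls per comparison in 10 runs and 0 shared ones. So few calls leave little room for shared ones, so this is no measure of what shared controls add to the overlap of real calls. With 3 controls, separate controls of at least 2 libraries for each protein could not be formed, so part of the excess may come from the shared controls. MAP3K8, IRAK2, STAT5A and NAB1, 4 genes in all (3.9 for independent lists), were lower with PDGF-BB and higher with S100A4. With the block 131 genes were (196.8 for independent lists), including CEBPD, TLR2 and NFKBIA, while 42 were higher with PDGF-BB and lower with S100A4 (129.5), including CCND1, TIMP3 and SDC1. The genes named in this comparison were chosen after their values were seen.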

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

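Among the tests in this part, that of endotoxin was chosen only after the result was seen. A test of the difference between the S100A4 effects without and with PDGF-BB, with replicate number as a block, marked 7 named genes. The differences on the log2 scale were −1.35 ± 0.11 for PTHLH (adjusted p = 0.00014), −1.31 ± 0.20 for LIF, −1.08 ± 0.15 for BDKRB2, −1 ± 0.17 for PMAIP1 and −0.77 ± 0.12 for NEDD4L. They were positive for TM4SF1 (0.60 ± 0.09) and IGFBP5 (0.43 ± 0.07). None of the 7 passed in edgeR without the block, where 0 of 12444 genes did, as with DESeq2 and limma-voom (152 at an unadjusted p under 0.05 in edgeR).

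Of the 14 genes with such a difference, 12 responded less to the combination than the product of the single responses. Normalization between libraries is argued against as the whole cause, since 14 kept their sign and threshold under RLE scaling and 13 under upper-quartile scaling. Increments that add on the count scale may account for part: for 8 genes that rose with each protein, the median log2 ratio of the combination to control plus both increments was −0.14 ± 0.08 (SD of 3 replicate numbers), but the members went both ways, from −0.79 ± 0.13 for PTHLH to 1.24 ± 0.37 for LIF, so the test leaves this open. Of 50 regroupings within replicate numbers, 5 gave at least 14 genes, the real one included. The other 4 (6556, 1473, 295 and 47 genes) placed 10 or 12 of 12 libraries by PDGF-BB or by S100A4. The regrouping with 6556 genes placed all 12 by PDGF-BB and that with 295 all 12 by S100A4. Both therefore tested the effect of that protein and are no measure of chance. Treatment effects may have raised the counts of 1473 and 47, though the remaining regroupings that placed 10 libraries this way gave 0 or 1 genes. Other regroupings, which placed at most 8 libraries by either protein, gave 0. The count of 5 is thus no measure of chance, which stays open. Without the block the real count was 0 in edgeR, DESeq2 and limma-voom, so the 50 regroupings drawn, with a highest of 660, decide nothing there.

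The replicate 2 libraries stood apart on PC1 in all 4 treatments. Sequencing depth is argued against, since thinning every library to the smallest total left PC1 with 49.2% of the variance, 0.986 of its former share, and replicate 2 still apart. Another cell type in the cultures is a candidate explanation: the median of 7 endothelial markers was higher in replicate 2 than in the mean of replicates 1 and 3 by 1.70 to 1.88 on the log2 scale, with TIE1 at 16.1 against 1.33 CPM and PECAM1 at 22.1 against 7.33 CPM, and that of 9 fibroblast markers by 1.62 to 1.8, with LUM at 721 against 266 CPM. Against a single source, the endothelial median differed between replicates 1 and 3 (−1.62), and ESAM was lower in replicate 2 (1.22 against 2.4 CPM). The endothelial median also rests partly on genes near the floor, since TEK averaged 0.406 CPM and EMCN 0.65 CPM over all libraries. LUM, DCN and PDGFRA also stand in other lists. The median of 5 macrophage markers lay between −0.20 and 0.18 in the 4 treatments. Averaged over the treatments, its members ran from −1.02 (LAPTM5) to 0.21 (CD68). A difference between animals stays open and untested, since no label ties a number to an animal.

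Of the 70 genes changed by S100A4, 69 were higher. Normalization between libraries is argued against as the whole cause, since at least 97.1% of the calls were higher under RLE and upper-quartile scaling and the median of all tested genes moved to no less than −0.037. With the replicate block 804 genes were higher and 532 lower, so the share over all calls depends on the model. Of the calls that changed 2-fold or more, 139 were higher and 7 lower with the block. On groups alone these were 44 and 1, so larger changes were mostly higher in both fits. Endotoxin in the protein preparation could raise NF-kB targets too, and the interferon-response list, which it raises in many cells, had a median of −0.29 (camera adjusted p = 0.97). That value decides nothing, because the design holds no inactivated or mock protein, so an effect of S100A4 itself and of endotoxin cannot be told apart.

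For each pair of groups the 6 libraries make 10 splits into groups of 3, and 1 of the 10, the real one, gave as many genes, so the share cannot be under 0.05. The real counts were 1830 for PDGF-BB, 70 for S100A4 and 2732 for the combination against control, 34 and 1862 for the combination against PDGF-BB and S100A4, and 1382 between the single treatments. The highest other split gave 0 in each, in edgeR without the block, and also among the splits that part all same-numbered pairs.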

How the results depend on the processing

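Leaving out replicate numbers for the agreement between effects and for the named genes was chosen only after the results were seen. No named value reversed: of 402 values, of which 167 passed in the fit on groups alone, 392 kept their side of the threshold under upper-quartile scaling, 3 were lost and 7 gained, and with the replicate block 0 were lost and 137 gained, while without replicates 1, 2 and 3 there were 104, 9 and 78 of the 167 lost. In the order PDGF-BB, S100A4 and both against control, both against PDGF-BB, both against S100A4, and S100A4 against PDGF-BB, the counts were 6075, 1336, 6982, 888, 5948 and 5367 genes with the replicate block, and 141, 28, 349, 6, 111 and 91 tested against a fold of 1.5, which asks for larger changes. With only the groups compared, and so fewer libraries for the spread, they were 1060 for PDGF-BB and 28 for S100A4 against control, 9 for both against PDGF-BB, 998 for both against S100A4 and 576 for S100A4 against PDGF-BB. DESeq2 called 199 genes for S100A4 against control and 118 for both against PDGF-BB, and the cause was not tested. Leaving out 1 replicate number gave, in the order above, 131 to 2139, 0 to 82, 502 to 3349, 0 to 39, 10 to 2507 and 5 to 1808 genes, each highest without replicate 2. With the block the leave-outs gave 608 to 1055 for S100A4 against control and 326 to 1306 for both against PDGF-BB. They gave 4372 to 5522 for PDGF-BB and 5312 to 6594 for both against control. For both against S100A4 they gave 4009 to 5904, and for S100A4 against PDGF-BB 3628 to 5075. The interaction gave 14 genes with the block, 58 in DESeq2 with the block, and 1 to 117 in its leave-outs. Under upper-quartile scaling the median of all tested genes was between −0.098 and 0.033 (−0.025 and 0.008 with TMM), and every count stayed within 1.5-fold, as under RLE scaling, no filter, the stricter filter and limma-voom. Of the gene list tests 29 passed, 1 with an estimated correlation, 47 with the replicate block, which kept all 29, and 21 with fry, which kept 19 of them. The S100A4 effects without and with PDGF-BB correlated across genes at r = 0.677, at 0.837 over genes with a mean of at least 3 log2 CPM, and at 0.58 to 0.638 with a replicate number left out, and the PDGF-BB effects at 0.844, 0.934 and 0.81 to 0.823. That genes with higher counts correlate better was not traced to a cause. On simulated counts without the block 35.8% of 1.5-fold changes and 81.8% of 4-fold changes were recovered for PDGF-BB against control, so changes of 1.5-fold were often missed. With the block 19 of 193 simulated calls were false for PDGF-BB, 15 of 204 for S100A4 and 18 of 184 for the interaction. Without it 0 were false in each. The shares with the block are above the threshold of 0.05, so counts with the block may hold more false calls than that threshold implies.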

Other observations

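In this part the list of 8 FOXO target genes was chosen only after its values were seen, as were the single genes of the next paragraph.

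In all 4 treatments 391 genes were more than 2-fold higher and 340 more than 2-fold lower in replicate 2 than in the mean of replicates 1 and 3. PROCR, the endothelial protein C receptor, averaged 177 CPM in replicate 2 and 3.57 CPM in the others, P-selectin SELP 158 and 8.95 CPM, CD34 85.7 and 10.4 CPM, the cytokine IL33 41.1 and 1.7 CPM, and ESM1 972 and 116 CPM. Interferon-induced genes were lower, with MX2 at 0.298 against 18.1 CPM and IFI6 at 16.1 against 168 CPM, and 19 of 19 tested members of the interferon list were lower in every treatment. Of 23 contractile genes 21 were lower in every treatment, with medians of −0.87 to −0.66. All 18 G2/M genes were higher in replicate 2 than in the mean of replicates 1 and 3 in every treatment (medians 1.24 to 1.57). Replicate 1 was above replicate 3 in them by a median of 1.73, so low values in replicate 3 account for part of this. In control replicates 1, 2 and 3 CCNB2 had 4.88, 5.39 and 3.17 log2 CPM, and HMMR 4.68, 4.56 and 3.14. NOTCH3, a receptor of mural cells, averaged 73.5 CPM in replicate 2 and 497 CPM in the others. Of 5 pericyte markers, NOTCH3 among them, 3 were lower and 2 higher in every treatment, with RGS5 at 6.57 against 0.963 CPM.

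Several genes lowered by PDGF-BB are known targets of FOXO transcription factors, which growth factor signalling keeps out of the nucleus. A list of 8 such genes picked from the values had all 8 lower, with a median of −1.72: FBXO32, TRIM63, CCNG2, CDKN1B, BMF, SESN1, KLHL24 and PIK3IP1. The hypothesis that FOXO activity was lower was tested on a longer list without these, written before its values were seen. Of 20 tested members 5 fell and 1 rose on groups alone, and 13 fell and 1 rose with the replicate block, with a median of −0.41. ULK1 (−1.01 ± 0.09), INSR (−0.85 ± 0.14), CDKN2B (−0.84 ± 0.12), FOXO3 (−0.73 ± 0.16) and BCL6 (−0.39 ± 0.07) fell, and TRIB1 rose (0.99 ± 0.22). The values are consistent with lower FOXO activity in PDGF-BB, but transcript levels do not measure the activity of the factors, and other regulators of the same genes were not tested.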
